A study of Homo sapiens with 4 samples.

How the data were processed

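Poly-A RNA was sequenced from 4 cultures of human breast cancer cells, 1 library each. MCF-7, an estrogen receptor-positive adenocarcinoma line, and TMR, a tamoxifen-resistant subline of it, were each given vehicle or 1 µM 4-hydroxytamoxifen (4-OHT) for 24 h. 4-OHT is the active metabolite of the antiestrogen tamoxifen. Per the labels' protocols, TMR had been kept in 1 µM 4-OHT for over 8 months, and all cells spent 2 days in phenol red-free medium with charcoal-stripped serum before treatment, which removes most estrogen. No drug is named for those 2 days, so whether TMR had 4-OHT then is not known. TMR with vehicle was thus withdrawn from 4-OHT for at least the 24 h. TMR with 4-OHT either had it returned or had it throughout. The libraries were made with a poly-A kit that does not mark strand and read as 100 bp pairs. Groups came from the sample labels, and no group holds a replicate.

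The deposited unit is FPKM, fragments per kilobase of transcript scaled to the mapped fragments of the library, with a lower and an upper bound per gene; per the file headers these are gene tracking tables. The submitters' processing notes name CASAVA 1.8, TopHat, Cufflinks and Cuffdiff, without versions for the last 3, and the builds GRCh37 and hg19, which hold the same chromosome sequences. The role and order of those tools, the gene annotation, the handling of reads that map to several places and the level of the bounds are not given in the sources used here. The authors' FPKM totals differed between libraries, so FPKM was not rescaled to a fixed total before deposit. No read counts entered, so the depth is unknown and no counting interval could be made. The deposited bounds spanned a median of 6.24% to 6.94% of the FPKM on either side, and between 84.2% and 86.8% of the FPKM values lay inside their own bounds. In the shortest 10% of transcripts the midpoint of the bounds lay at a median of 0.931 to 0.945 of the FPKM, depending on the library. The bounds describe 1 library each and carry no variation between cultures.

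Each table held 24934 rows and 23284 symbols. A total of 28 symbols that had been turned into dates in the gene column were read from the identifier column instead. The 12 rows with a failed estimate in any library were left out, a choice made after the files had been read. A symbol on several rows, 543 in all, was taken as the row with the highest mean FPKM. Genes with FPKM of at least 1 in at least 1 of the 4 libraries were kept, 13030 in all. Differences were taken as log2(FPKM + 1) of one library minus that of another, a scale that understates the difference of low genes, and genes were counted at a 2-fold size on that scale. The comparisons were 4-OHT against vehicle in MCF-7, 4-OHT against vehicle in TMR, TMR against MCF-7 with vehicle, TMR against MCF-7 with 4-OHT, and the TMR response minus the MCF-7 response. With 1 library per group there was no test and no p-value. The 5 comparisons share libraries.

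The 35 gene lists were written down from general knowledge. They cover estrogen-induced and estrogen-repressed genes, luminal identity, basal and mesenchymal markers, growth factor receptors and ligands, the NRF2 antioxidant response, other antioxidant enzymes, TIGAR and its reported partners, glycolysis, the pentose phosphate pathway, the TCA cycle and glutamine, oxidative phosphorylation, cholesterol synthesis, fatty acid synthesis, sterol efflux, G1-S and DNA replication, G2-M and mitosis, and CDK inhibitors with p53 targets. They also cover apoptosis regulators, the amino acid and ER stress response, heat shock chaperones, lysosome and autophagy, the interferon response, antigen presentation, inflammatory and NF-kB genes, aryl hydrocarbon receptor targets, drug transport and tamoxifen metabolism, histone methyltransferases and demethylases, nuclear receptors and coregulators, hypoxia, immediate-early genes, fibroblast, endothelial and blood cell markers, cytosolic ribosomal proteins, replication-dependent histones and housekeeping genes. Each list's median log2 difference was placed among 10000 random lists of the same size, matched on mean expression in 20 bins, and the percentile describes these libraries only. Some lists share members.

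The named genes followed a rule. For each 4-OHT response these were the 12 genes with the largest difference in each direction that had FPKM of at least 5 in at least 1 of the 2 libraries and bounds that did not overlap. For TMR against MCF-7 the ranking used the mean of both treatments, with both at least 2-fold in the same direction. For the difference of responses 6 genes in each direction were taken. Symbols of small or non-coding RNA were left out where a fixed set of prefixes and endings recognised them, which does not cover RPPH1, RMRP, BCYRN1 and MALAT1, and up to 4 members of each list were named. Any other gene named was chosen after its values were seen, and the text says so. The rule, the lists, the comparisons, the filter, the pseudocount of 1 and most alternatives were set before the data were examined.

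Those set beforehand were pseudocounts of 0.1 and 5, no filter or FPKM of at least 5, rescaling to the same total, by median of ratios or to the same upper quartile, leaving out small and non-coding RNA by the same symbols, summing repeated symbols, requiring bounds that do not overlap, matching random lists in 5 bins or not at all, the mean of a list, and members held by no other list. The following were added after the data were seen: removal of the trend of the log2 differences over transcript length and then GC content by lowess (fraction 0.2), transcripts of at least 1500 nt, failed estimates kept at 0, rows with little data left out, and the line comparison without the TMR vehicle library. Transcript length and GC content came from GENCODE release 29 (GRCh38), used only for those properties, and were found for 12494 of the genes kept (95.9%). Matching by unique older symbols was also added after first results had been seen. Coordinates are those of the deposited tables, on hg19, counted from 1.

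The agreement of responses was a correlation across genes, which are not independent replicates, with a 95% interval from 2000 resamples of genes. The relation between the line difference and the MCF-7 response shares libraries, so it was given as a covariance beside the value from 100 simulated draws with no effects. Differences of response were marked for a closer look where both list medians lay beyond percentiles 2.5 and 97.5 with opposite signs, or where a named gene differed at least 2-fold in opposite directions with bounds apart in both lines. The steps were tested on simulated data for the MCF-7 response over 11991 genes: 100 of 100 genes simulated at 3-fold and 0 of 100 at 1.5-fold were counted at 2-fold, and 5 of 11761 unchanged genes were counted. The simulated noise came only from the bounds of the MCF-7 vehicle library, with no variation between cultures. These counts therefore check the calculation and give no error rate for the counts in the real libraries. A list of genes shifted by 0.5 on the log2 scale gave a median of 0.48 at percentile 100. For a simulated length trend in the TMR response the correlation with log2 length went from -0.966 to -0.0942, so the removal was close but not complete; the limit this step had to meet was loosened after that value was seen. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used. Reads were not realigned, and isoforms were not analysed here.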

Results

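Gene expression was measured by poly-A RNA sequencing in MCF-7 breast cancer cells and in TMR, their subline selected for growth in 4-hydroxytamoxifen (4-OHT), each with vehicle or with 1 µM 4-OHT for 24 h. There was 1 library in each of the 4 groups, so there are no replicates and each difference below has no replicate check. Values are the deposited FPKM, and differences are on the log2(FPKM + 1) scale. Read depth is unknown, since no counts entered. FPKM totals were 435188 in MCF-7 with vehicle, 399016 in MCF-7 with 4-OHT, 281446 in TMR with vehicle and 437583 in TMR with 4-OHT. Between 11854 and 12188 genes reached FPKM 1 per library. The TMR vehicle library stood apart from the other 3: the median FPKM of cytosolic ribosomal protein genes was 232 there, against 1063, 961 and 900 in MCF-7 with vehicle, MCF-7 with 4-OHT and TMR with 4-OHT. Every comparison below that uses the TMR vehicle library holds that difference. Rescaling the libraries to the same total moved the median of all genes by -0.51 in the TMR response to 4-OHT, by 0.54 in the line comparison with vehicle, by -0.12 in the line comparison with 4-OHT and by -0.61 in the difference of responses. Rescaling to the same upper quartile moved these medians by -0.14, 0.0040, -0.22 and -0.21, median of ratios moved the 4-OHT line comparison by -0.15, and removal of the length and GC trend moved it by -0.19. Directions that turned under a rescaling are named with it.

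The series concerns TIGAR, a fructose-2,6-bisphosphatase that lowers glycolytic flux, and NRF2, the transcription factor of the antioxidant response, so these were read first. TIGAR, listed as C12orf5 (chromosome 12, 4430359 to 4469190, hg19), had FPKM 1.01 (deposited bounds 0.909 to 1.12) in MCF-7 with vehicle and 0.998 (0.898 to 1.10) with 4-OHT. In TMR it had 2.53 (2.35 to 2.71) with vehicle and 2.47 (2.30 to 2.65) with 4-OHT, a log2 difference between lines of 0.81 and 0.80. NFE2L2, the gene of NRF2 (chromosome 2, 178095031 to 178129859), had FPKM 28.3, 27.2, 27.9 and 25.5 in MCF-7 with vehicle, MCF-7 with 4-OHT, TMR with vehicle and TMR with 4-OHT. Its line difference was -0.02 with vehicle, which turned to 0.59 at the same total, and -0.09 with 4-OHT. WHSC1, the gene of the histone methyltransferase NSD2 (chromosome 4, 1873123 to 1983934), had 16.2 and 13.4 in MCF-7 and 47.7 and 36.9 in TMR. ESR1, the gene of estrogen receptor alpha (chromosome 6, 152011631 to 152424408), was lower in TMR, at FPKM 19.2 and 15.1 against 61.5 and 42.9. PGR, the progesterone receptor gene and an estrogen target (chromosome 11, 100900355 to 101000544), was higher in TMR, at 4.89 and 2.98 against 0.705 and 1.66.

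The list of TIGAR and its reported partners had a median of 0.40 between the lines with vehicle (percentile 94.7 of random lists) and 0.36 with 4-OHT (74.3), with 3 of 8 members at least 2-fold higher in both. The direction rests on WHSC1, HK2 and PFKFB3 with TIGAR: it turned to -0.98 and -0.40 for TP53 and FBP1, the members that no other list holds, and to -0.02 and -0.08 among members with FPKM of at least 5. HK2, a hexokinase, was higher in TMR by 1.91 and 1.49, and PFKFB3, which makes fructose-2,6-bisphosphate, by 1.58 and 1.11. FBP1, a gluconeogenic phosphatase, was lower in TMR by -1.72 with vehicle and -0.72 with 4-OHT. The medians of this list after 4-OHT were -0.06 in MCF-7, which turned to 0.05 at the same total and 0.01 at the same upper quartile, and -0.08 in TMR, which turned to 0.03 for the mean in place of the median. For TP53 and FBP1 alone they were -0.24 in MCF-7 and 0.34 in TMR.

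**Figure D1:**
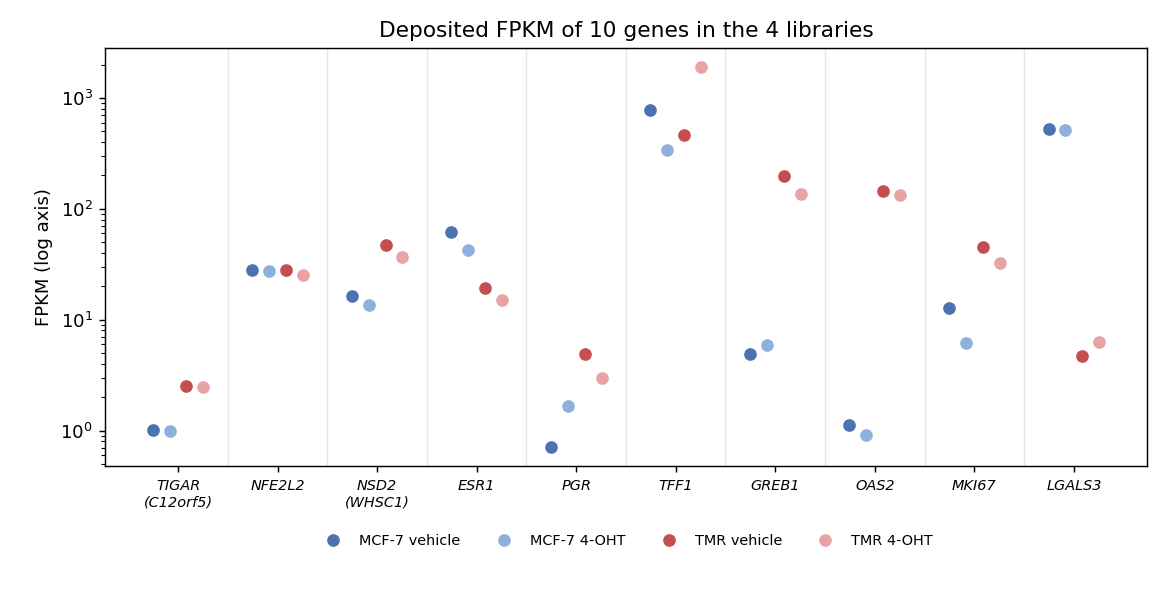
FPKM on a log axis of single genes in each of the 4 libraries, 1 point per library. TIGAR (C12orf5) lies at FPKM 1.01 and 0.998 in the MCF-7 libraries and at 2.53 and 2.47 in the TMR libraries, while NFE2L2 lies between 25.5 and 28.3 in all 4.

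The first comparison asked what 24 h of 4-OHT does in the drug-sensitive parental cells, and genes of the cell cycle were lower. The G2-M and mitosis list had a median of -0.87, below all 10000 random lists, and 29 of its 32 members were at least 1.5-fold lower and 9 at least 2-fold lower. BIRC5 (survivin, of the chromosomal passenger complex) was lower by -1.25, AURKB (its kinase) by -1.17, and UBE2C (a ubiquitin-conjugating enzyme of the anaphase-promoting complex) by -1.14. The G1-S and DNA replication list had a median of -0.70, again below all random lists, with 24 of 35 members at least 1.5-fold lower. TK1 (thymidine kinase) was lower by -1.47, E2F1 (a G1-S transcription factor) by -1.24, GINS2 and CDC45 (of the replicative helicase) by -1.23 and -1.20. SPC24 (a kinetochore protein), RECQL4 (a DNA helicase) and CDCA5 (sororin, a cohesin regulator) were lower by -1.48, -1.19 and -1.19. MKI67, a proliferation marker named here after its values were seen, had FPKM 12.9 with vehicle and 6.19 with 4-OHT.

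Estrogen targets went both ways in MCF-7 after 4-OHT. The list of estrogen-induced genes had a median of 0.20, above all random lists, with 11 of 50 members at least 1.5-fold higher and 4 at least 1.5-fold lower. CXCL12 (a chemokine) was higher by 2.25, SERPINA1 (alpha-1-antitrypsin) by 2.05 and RAPGEFL1 by 1.37, while TFF1 and TFF3, the trefoil peptides, were lower by -1.19 and -1.21. TFF1 had FPKM 775 with vehicle and 339 with 4-OHT. Of the other genes named by the rule, KRT13, a keratin of squamous epithelia, had the largest difference, at FPKM 1.96 with vehicle and 26.5 with 4-OHT. PHLDA1 was higher by 1.87, SEMA3B (a semaphorin) by 1.67, AMZ1 by 1.65, ANXA9 (an annexin) by 1.60, TMEM120B by 1.49, AGR3 (of the anterior gradient family) by 1.47 and UGT2B15 (a steroid glucuronosyltransferase with close paralogs) by 1.52. RPPH1 and RMRP, the RNA parts of RNase P and RNase MRP, were higher by 2.35 and 2.06. These RNAs are short and lack a poly-A tail, so their FPKM in poly-A libraries is uncertain.

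Other lists differed little in MCF-7. Drug transport and tamoxifen metabolism had a median of 0.16 (percentile 99.9), with UGT2B15 and UGT2B17 (0.88) at its top. Immediate-early genes had 0.13 (percentile 100), apoptosis regulators 0.12 (99.9), growth factor receptors and ligands 0.08 (99.3), cholesterol synthesis 0.06 (99.9), and nuclear receptors 0.09 (99.6). FOS, an early transcription factor, was higher by 0.82, and GFRA1, a receptor of glial-derived factors, by 0.78. Estrogen-repressed genes had -0.07 (percentile 40.9), which turned to 0.04 at the same total, and CDK inhibitors with p53 targets had -0.08 (31.1), which turned to 0.03 there. The luminal identity list had -0.03 (97.8), which turned to between 0.0068 and 0.09 under the 3 rescalings and 0.11 with the length and GC trend removed. The NRF2 list had -0.17 (1.91), with NQO1, a quinone reductase, at -0.56, and oxidative phosphorylation had -0.20 (0.95). In all, 70 genes were at least 2-fold higher and 54 lower, of which 22 and 11 had symbols of small or non-coding RNA. That split was 86 to 29 at the same total, 84 to 41 at the same upper quartile and 72 to 36 with the length and GC trend removed. It was 48 to 43 with small and non-coding RNA left out. The balance turned to 48 to 52 at FPKM of at least 5 and to 142 to 160 with a pseudocount of 0.1.

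The second comparison asked what the same treatment does in the resistant subline. TMR had been grown in 4-OHT, so its vehicle library follows withdrawal of the drug. No drug is named for the 2 days before treatment, so its 4-OHT library follows either the drug's return or its continued presence. The word response covers all of these here. Ribosomal protein and oxidative phosphorylation transcripts were higher with 4-OHT: the ribosomal protein list had a median of 1.88, above all random lists, and 36 of its 38 members were at least 2-fold higher. RPL36 was higher by 2.84, RPL35 by 2.66, RPS29 by 2.65 and RPS21 by 2.63, all proteins of the cytosolic ribosome. RPL21, with many pseudogenes, was higher by 2.65. The oxidative phosphorylation list had a median of 1.52, above all random lists, with 23 of 35 members at least 2-fold higher, and NDUFA3 and NDUFB7 of complex I were higher by 2.89 and 2.71, ATP5I of the ATP synthase by 2.83. TCEB2 (elongin B), ROMO1 (a small mitochondrial membrane protein) and C4orf48 were higher by 2.78, 2.66 and 2.70. BCYRN1, the brain cytoplasmic RNA related to Alu repeats, was higher by 2.97 and is uncertain, since its reads match many places. For the same genes the TMR vehicle library was the low one of the 4: RPL36 had FPKM 109 there and 779, 679 and 789 in MCF-7 with vehicle, MCF-7 with 4-OHT and TMR with 4-OHT.

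These differences followed transcript length. The median TMR response was 0.96 in the shortest 10% of transcripts and -0.37 in the longest 10%, against -0.14 and 0.10 for the MCF-7 response. In all 933 genes were at least 2-fold higher in TMR after 4-OHT and 24 lower. Counted anew in each setting, the split was 195 to 271 with the length and GC trend removed, 154 to 0 among transcripts of at least 1500 nt, and 324 to 1196 at the same total. With that trend removed the ribosomal protein median was 0.84 and that of oxidative phosphorylation 0.53.

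**Figure D2:**
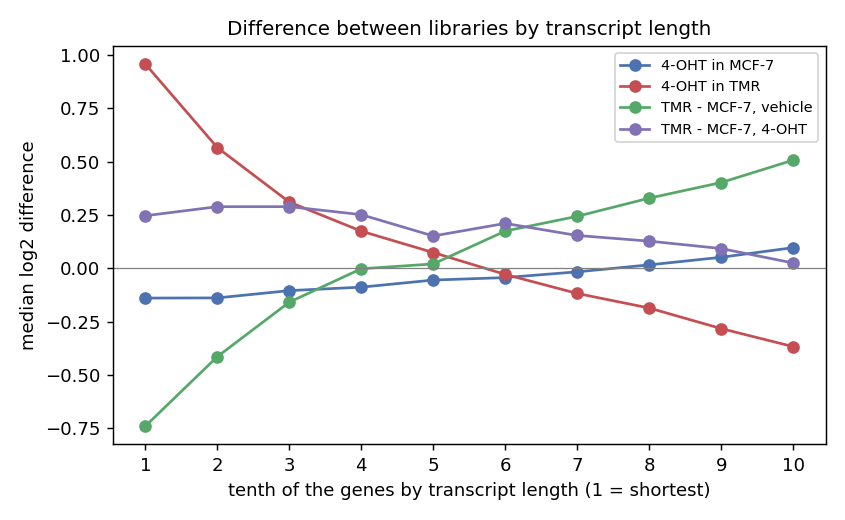
Median log2 difference of genes in 10 groups of rising transcript length, 1 line per comparison. The TMR response runs from 0.96 to -0.37 and the vehicle comparison of the lines from -0.74 to 0.51, while the 2 comparisons without the TMR vehicle library stay between -0.14 and 0.29.

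The cell cycle lists showed little difference in TMR after 4-OHT. The G2-M median was 0.01 (percentile 35.2), which turned to between -0.60 and -0.07 under the 3 rescalings and -0.04 with the trend removed, and no member was at least 1.5-fold lower. The G1-S median was 0.16 (percentile 78.0), which turned to -0.43 at the same total and -0.02 at the same upper quartile. TK1 had FPKM 58.7 with vehicle and 112 with 4-OHT in TMR, against 43.4 and 15.1 in MCF-7. TFF1 and TFF3 were higher in TMR by 2.04 and 1.81, with TFF1 at FPKM 463 with vehicle and 1907 with 4-OHT, and both are short transcripts; with the trend removed they were higher by 0.65 and 0.92. The estrogen-induced list as a whole had -0.05, inside the random lists (percentile 4.94), which turned to 0.10 for the mean in place of the median and was -0.59 at the same total.

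Antioxidant genes were higher with 4-OHT in TMR, and their list medians shrank with the length and GC trend removed. The other antioxidant enzymes had a median of 0.99 (percentile 100), led by PRDX5 (a peroxiredoxin) at 1.94 and GPX4 (the phospholipid peroxidase) at 1.60, and the median was 0.23 with the trend removed, still at percentile 99.3. The NRF2 list had 0.49 (97.9), which turned to -0.12 at the same total and was 0.06 with the trend removed, inside the random lists (44.2). TXN (thioredoxin) was higher by 1.56 and PRDX1 by 1.07. Antigen presentation had 0.67 (percentile 100) and 0.15 with the trend removed, with the immunoproteasome subunit PSMB9 at 1.55. Replication-dependent histones had 0.52 (100), which turned to -0.04 at the same total and -0.18 with the trend removed. The inflammatory and NF-kB genes had 0.31 (99.7), which turned to -0.21 at the same total.

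Long transcripts were lower. Histone methyltransferases and demethylases had a median of -0.27 (percentile 0.03), with MLL (KMT2A) at -0.78 and MLL3 (KMT2C) at -0.69, and nuclear receptors and coregulators had -0.31 (0.07), with AR (androgen receptor) at -0.64; with the trend removed these medians were -0.06 and -0.11. Of the genes named by the rule, RMRP and RPPH1 were lower by -4.43 and -3.34. WASH5P, RPS10P7, SPDYE6, SPDYE7P, SPDYE2 and POTEF, members of families with near-identical copies and so uncertain, were lower by -1.02, -0.95, -0.89, -0.89, -0.81 and -0.83. MALAT1 (a nuclear non-coding RNA) had FPKM 113 with vehicle and 55.9 with 4-OHT, and LPP (a focal adhesion protein), NFAT5 (the osmotic stress factor) and MDM4 (a p53 inhibitor) were lower by -0.86, -0.85 and -0.82. Of the 24 genes lower by 2-fold, 20 had symbols of small or non-coding RNA, and the others were RMRP, RPPH1, WASH5P and C1orf151-NBL1, the last named after its value was seen.

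The remaining lists had modest medians in TMR. Heat shock chaperones had 0.43 (percentile 37.3), the pentose phosphate pathway 0.49 (92.3) and luminal identity 0.32 (19.6). Lysosome and autophagy had 0.31 (82.0), housekeeping genes 0.34 (19.4) and the TCA cycle 0.30 (82.4). All of these turned negative at the same total, and luminal identity also turned to -0.07 among transcripts of at least 1500 nt. The interferon list had 0.12 (73.0), which turned to -0.40 at the same total, -0.02 at the same upper quartile and -0.09 among transcripts of at least 1500 nt, though ISG15, a ubiquitin-like interferon product of short transcript, was higher by 2.31. Fatty acid synthesis had -0.18 (1.83), hypoxia -0.15 (3.37) and growth factor receptors and ligands -0.13 (8.74).

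The third question was whether the response to 4-OHT differed between the lines; it could be described but not tested. The TMR response minus the MCF-7 response had a median of 0.88 for the G2-M list and 0.85 for the G1-S list, both above all random lists, with UBE2C at 2.10, BIRC5 at 1.87 and TK1 at 2.39. Both medians stayed positive at the same total, at 0.14 and 0.11, where the median of all genes moved by -0.61. TFF1 (3.23), TCEB2 (3.13), C4orf48 (3.19), TMEM160 (3.17), RPL21 (3.15) and BCYRN1 (3.88) had the largest positive differences of response. RMRP (-6.50), RPPH1 (-5.69), KRT13 (-2.95), CXCL12 (-2.42), RAPGEFL1 (-1.82) and AMZ1 (-1.82) had the most negative ones. KRT13 was higher by 0.27 in TMR after 4-OHT, against 3.21 in MCF-7. CXCL12 already had FPKM 36.0 in TMR with vehicle, above the 29.6 of MCF-7 with 4-OHT. Growth factor receptors and ligands had a difference of -0.23 and the estrogen-induced list one of -0.12 (percentile 0.35). In all 1421 genes were positive by at least 1 on the log2 scale and 193 negative, a split of 438 to 2682 at the same total, 1158 to 328 by median of ratios, 952 to 531 at the same upper quartile and 348 to 458 with the length and GC trend removed.

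Across genes the 2 responses, which share no library, had a correlation of -0.28 (95% interval over genes -0.32 to -0.24; 0.0049 in simulated draws with no effects), and -0.18 with the trend removed. Of the 124 genes at least 2-fold different in MCF-7, 41 (33.1%) had the same direction in TMR. TFF1 and TFF3 were among 8 genes lower in MCF-7 and higher in TMR by 2-fold, where independent lists would share 3.87. RMRP and RPPH1 were among 6 higher in MCF-7 and lower in TMR (0.129 for independent lists). A total of 4 were higher in both (5.01) and 3 lower in both (0.0995). With symbols of small and non-coding RNA left out, FAM25A and SPINK4 were higher in both (3.45 for independent lists), no gene was lower in both, RMRP and RPPH1 stayed in opposite directions (0.0154), and 5 genes were lower in MCF-7 and higher in TMR (3.09); FAM25A and SPINK4 are named after their values were seen. The difference of TMR from MCF-7, over the mean of both treatments, showed little relation to the MCF-7 response. The covariance was -0.0084 (interval over genes -0.019 to 0.0026, simulated -8.9e-05) and the correlation -0.03. With the trend removed the covariance was -0.016 and the correlation -0.05. The covariance lay below that interval with a pseudocount of 0.1 and in transcripts of at least 1500 nt. With vehicle alone the covariance was 0.070 (simulated 0.0035) and with 4-OHT alone -0.086 (simulated -0.0037). Each of these shares a library with the MCF-7 response, in opposite ways. The simulated draws used only the spread that the deposited bounds give, with no variation between cultures. They can therefore understate the effect of a shared library, and no conclusion is drawn from the gap.

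The fourth comparison set TMR against MCF-7, and interferon-response genes were the most elevated list. Its median was 2.58 with vehicle and 3.14 with 4-OHT, above all random lists, and 27 and 30 of 34 measured members were at least 2-fold higher in TMR. OAS2 (an antiviral oligoadenylate synthetase, chromosome 12, 113416274 to 113449528) had FPKM 1.13 and 0.913 in MCF-7 and 144 and 134 in TMR. IFI27, IFIT1, IFI44, XAF1 and BST2 (tetherin), all induced by interferon, were higher by a mean of 5.57, 5.35, 5.31, 5.29 and 4.95 over both treatments; IFIT1 has close paralogs. Antigen presentation had medians of 0.66 (percentile 99.7) and 1.38 (100), with HLA-B, a class I molecule whose reads overlap other HLA genes, higher by 2.25 and 3.03 and the immunoproteasome subunits PSMB9 and PSMB8 by 3.69 and 3.26 with 4-OHT. HLA-DRB1, a class II chain, was lower by -2.35 with vehicle.

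Cell cycle genes were also higher in TMR. The G2-M list had medians of 1.36 and 2.29, above all random lists, with 24 and 32 of 32 members at least 2-fold higher, and the G1-S list had 0.66 and 1.61, with 10 and 28 of 35. TPX2 (a spindle factor) was higher by 2.05 and 2.95, and PLK1 (polo-like kinase) by 1.55 and 2.74. CDK6, a G1 kinase, went the other way, at FPKM 7.77 and 8.57 in MCF-7 and 0.369 and 0.210 in TMR.

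Several metabolic lists were higher in TMR. Hypoxia-response genes had medians of 1.25 and 1.16, fatty acid synthesis 1.26 and 0.99, and glycolysis 0.81 and 1.10, each at percentile 100 in both treatments. BHLHE40, a hypoxia-induced repressor, was higher by 4.68 and 3.91 and VEGFA, the endothelial growth factor, by 2.23 and 2.15. SCD, the stearoyl-CoA desaturase, was higher by 1.89 with vehicle, and ACLY, ATP citrate lyase, by 1.65 and 1.55. LDHA (lactate dehydrogenase) was higher by 2.62 with 4-OHT and SLC16A1 (a lactate transporter) by 2.58 and 2.49. Cholesterol synthesis had 0.43 (percentile 99.7) and 0.46 (94.0), and the amino acid and ER stress list 0.35 (99.1) and 0.62 (99.8), led by SLC7A5, the leucine transporter, at 5.11 and 4.70 and PSAT1, of serine synthesis, at 3.40 and 3.39. The pentose phosphate pathway had -0.51 (13.1) with vehicle, which turned to 0.06 at the same total, and 0.18 (56.4) with 4-OHT, which turned to -0.07 at the same upper quartile and -0.17 with the trend removed. The TCA cycle had -0.23 (34.0) with vehicle, which turned to 0.38 at the same total, and 0.24 (62.4) with 4-OHT. Heat shock chaperones had 0.24 (99.8) and 0.74 (99.9), and HSPB8 had FPKM 106 and 140 in TMR against 1.43 and 5.03 in MCF-7.

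Estrogen targets were higher on balance in TMR, with list medians of 0.84 (percentile 100) and 0.52 (99.8), although ESR1 itself was lower. Over the alternatives these medians ranged from 0.52 to 1.42 with vehicle and from 0.22 to 0.66 with 4-OHT, where members that no other list holds had 0.29 and transcripts of at least 1500 nt 0.22. GREB1, an estrogen receptor cofactor and target, had FPKM 4.90 and 5.86 in MCF-7 and 196 and 137 in TMR. SUSD3 was higher by 3.47 and 4.14, while AGR2 was lower by -5.58 and -4.79, and 8 of 50 members were at least 2-fold lower in each treatment. Estrogen-repressed genes had -0.39 (0.31) with 4-OHT and -0.02 with vehicle, which turned to 0.58 at the same total, and KLF4 (a Krüppel-like factor) was lower by -3.31 and -3.22. Growth factor receptors and ligands had a median of 0.01 (44.7) with vehicle, with 6 members at least 2-fold higher and 4 lower. That median turned to -0.07 by median of ratios and -0.02 at the same upper quartile. With 4-OHT the list had -0.02 (16.3), with 5 members higher and 7 lower. Among the higher members FGFR1 and FGFR4 were higher by 3.44 and 3.34 with vehicle and AREG (amphiregulin) by 3.10. Within the nuclear receptors NR2F2 (COUP-TFII) was lower by -5.73 and -5.57 and VDR (the vitamin D receptor) higher by 2.88 and 2.72. BCL2, the antiapoptotic protein, was higher by 3.22 and 2.64, and MYC by 2.73 and 2.82. The apoptosis regulators as a list had -0.0043 (39.8) with vehicle, which turned to 0.61 at the same total. With 4-OHT they had 0.21 (55.4), which turned to -0.04 at the same upper quartile.

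The genes with the largest differences included TARP, at FPKM 0.141 and 0.219 in MCF-7 and 159 and 276 in TMR. It overlaps the T cell receptor gamma locus (chromosome 7, 38299244 to 38313248), so its reads are uncertain. PLS3 (plastin, an actin bundler), IL20 (a cytokine), SCIN (scinderin, an actin-severing protein) and ASCL1 (a neural transcription factor) were higher by a mean of 5.89, 5.83, 5.00 and 4.92. In the other direction CA2 (carbonic anhydrase) had FPKM 74.2 and 160 in MCF-7 and 0.0434 and 0.105 in TMR. LGALS3 (galectin-3, chromosome 14, 55595935 to 55612148) had 520 and 509 in MCF-7 and 4.73 and 6.24 in TMR. S100P (a calcium-binding protein), C19orf63, SCUBE2, SOX2 (a stem cell factor) and CAPN9 (a calpain) were lower by a mean of -5.95, -6.12, -5.30, -5.20 and -4.58. LCN2 (lipocalin) and RAMP3 (a receptor accessory protein) had FPKM 61.0 and 55.3 in MCF-7 with vehicle and were listed at 0 in TMR with vehicle. CTSF (cathepsin F) had 18.5 in MCF-7 with 4-OHT and was listed at 0 in TMR with 4-OHT.

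**Figure D3:**
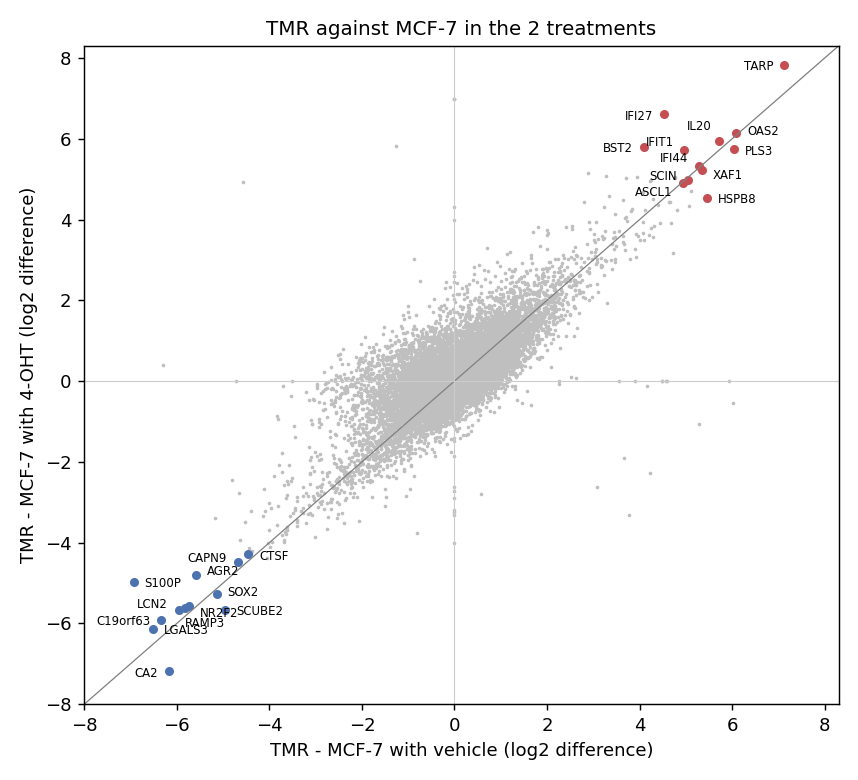
Log2 difference of TMR from MCF-7 with vehicle (horizontal) and with 4-OHT (vertical), 1 point per gene, with the genes named by the rule in colour and the line of equal difference. Named genes have the same direction on both axes, from -7.18 for CA2 to 7.83 for TARP with 4-OHT; IFI27 (4.53 and 6.61) and BST2 (4.10 and 5.80) are among those off the line of equal difference.

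The NRF2 list had a median of -0.69 (percentile 0.44) in TMR with vehicle. It was -0.03 at the same total, -0.02 among transcripts of at least 1500 nt and -0.19 with the trend removed, inside the random lists (43.0). With 4-OHT the list was near 0, at 0.0073 (14.3), which turned to between -0.24 and -0.08 under the 3 rescalings and -0.19 with the trend removed. AKR1C3, AKR1C2 and AKR1C1, aldo-keto reductases with near-identical sequences, were lower with vehicle by -4.63, -3.82 and -2.23. NQO1 had FPKM 297 and 201 in MCF-7 and 115 and 197 in TMR. Ribosomal proteins had -2.04 (percentile 0) with vehicle and -0.11 (10.2) with 4-OHT, and oxidative phosphorylation -1.06 (0.295) and 0.49 (99.4). With the trend removed the vehicle medians were -1.38 (percentile 0) for ribosomal proteins and -0.26 (69.5), inside the random lists, for oxidative phosphorylation, which was -0.45 at the same total.

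Sterol efflux genes were lower in TMR with vehicle, at -0.93 (percentile 0.27). With 4-OHT their median of -0.27 lay inside the random lists (6.34), with 2 of 8 members at least 2-fold higher and 3 lower, and it was -0.02 at FPKM of at least 5. With vehicle, histone methyltransferases and demethylases had 0.39 (96.6), basal and mesenchymal markers -0.24 (11.5), lysosome and autophagy -0.38 (11.9) and aryl hydrocarbon receptor targets -0.54 (5.93); the last 3 turned positive at the same total, and the last also to 0.29 for members that no other list holds and 0.14 with no filter on low values. WHSC1 was higher by 1.39 with 4-OHT, SMYD3 (a methyltransferase) was lower by -2.76 with vehicle, and CYP1B1, an aryl hydrocarbon receptor target, was lower by -3.41. With 4-OHT, lysosome and autophagy had -0.19 (0.61) and drug transport and tamoxifen metabolism -0.39 (1.20). Of the latter list 12 of 23 entries passed the filter, and its median was -0.01 with no filter on low values. Of the 23 fibroblast, endothelial and blood cell markers only ACTA2, COL1A1, HBA1 and CD68 passed the filter, with a median of 0.79 (88.8) with vehicle and 1.68 (99.6) with 4-OHT; ACTA2, smooth muscle actin, was higher by 1.73 and 2.38, and HBA1, alpha globin, by 0.31 and 2.39. Housekeeping genes had 0.04 with vehicle, which turned to -0.0083 by median of ratios and -0.04 for the mean in place of the median.

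In all 1765 genes were at least 2-fold higher and 1752 lower in TMR with vehicle, and 1932 and 973 with 4-OHT. The split with vehicle was 4131 to 875 at the same total. That with 4-OHT was 1547 to 1249 by median of ratios, 1403 to 1402 at the same upper quartile and 1365 to 1267 with the length and GC trend removed. A total of 1168 genes were higher in both treatments and 708 lower in both, 945 and 871 with the trend removed, while 24 went opposite ways. The comparison with 4-OHT does not use the TMR vehicle library.

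**Figure D4:**
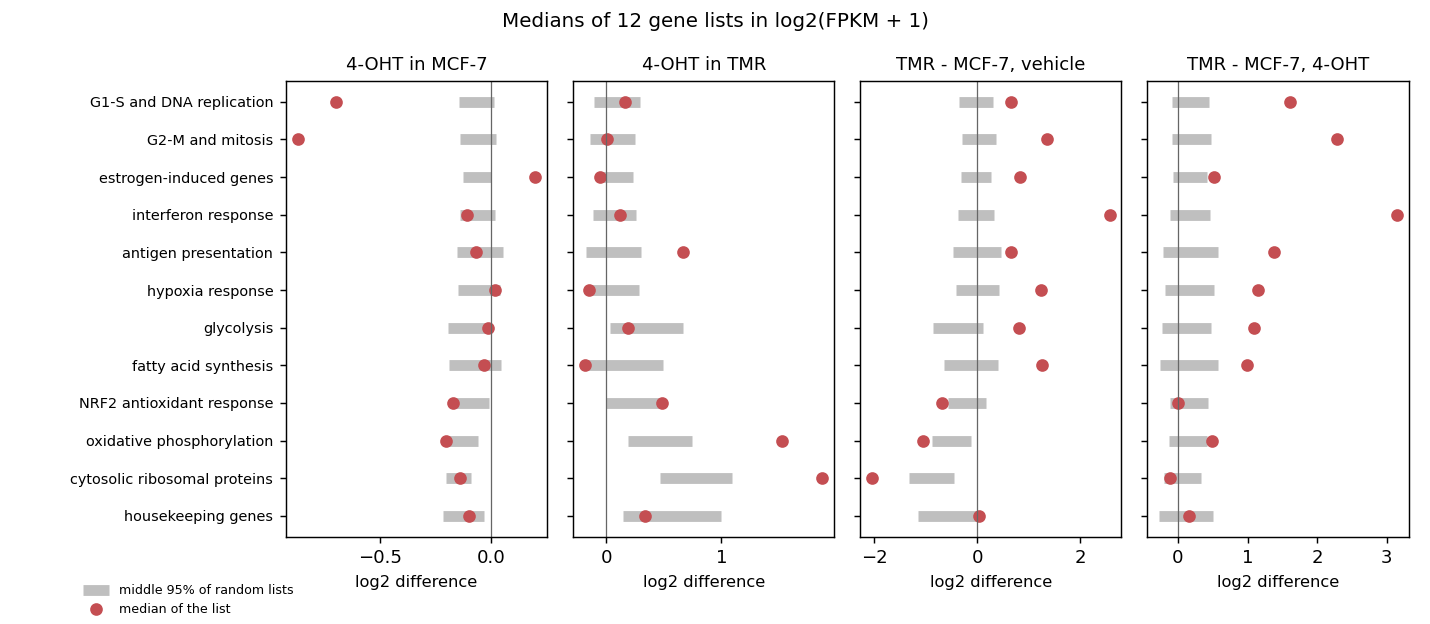
Medians of 12 gene lists (points) in log2 difference for 4 comparisons, with the middle 95% of random lists of matched expression as grey bars. G1-S and G2-M lists lie left of the bars in MCF-7 after 4-OHT, at -0.70 and -0.87, and within them in TMR, at 0.16 and 0.01, which turn to -0.43 and -0.60 at the same total and -0.02 and -0.17 at the same upper quartile; the interferon list lies at 2.58 and 3.14 between the lines. Points and bars are on the deposited scale, so the rescaled values are not to be read against the bars. At the same total the median of all genes in TMR was itself -0.51.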

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

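The tests of explanations in this part were chosen after the results were seen, while the differences of response come from a comparison set beforehand.

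On the deposited scale the response to 4-OHT went opposite ways in the 2 lines for 4 gene lists and, among genes named by the rule, 4 genes. Each difference was seen with 1 library per group and was not tested. The MCF-7 medians were small: -0.20 for oxidative phosphorylation, -0.17 for NRF2, 0.04 for histone methyltransferases and demethylases and 0.09 for nuclear receptors and coregulators. In MCF-7 all 35, 32 and 33 measured members of the former lists, and 20 of 21 of the last, were within 1.5-fold. TFF1 and TFF3, the trefoil peptides, were lower in MCF-7 and higher in TMR, with differences of response of 3.23 and 3.02. RMRP and RPPH1, the RNA parts of RNase MRP and RNase P, were higher in MCF-7 and lower in TMR, with -6.50 and -5.69. Oxidative phosphorylation differed by 1.68 and the NRF2 list by 0.66, and with the length and GC trend removed by 0.52 and 0.17; at the same total the NRF2 difference turned to -0.06 and its median was negative in both lines, at -0.05 in MCF-7 and -0.12 in TMR. Histone methyltransferases and demethylases differed by -0.32 and nuclear receptors and coregulators by -0.37, and with that trend removed by -0.02 and -0.15, where the former list was negative in both lines, at -0.02 in MCF-7 and -0.06 in TMR. With the trend removed none of the 4 lists met the rule for a closer look. Oxidative phosphorylation lay at percentile 16.7 in MCF-7 and NRF2 at 44.2 in TMR. Histone methyltransferases lay at 39.4 in MCF-7 and 9.48 in TMR, and nuclear receptors at 88.3 and 5.04. All of these differences use the TMR vehicle library, in which short transcripts were lower as a group. RMRP and RPPH1, which are short too, went the other way in TMR, with higher values with vehicle than with 4-OHT. They lack a poly-A tail, so their FPKM in poly-A libraries is uncertain.

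Short transcripts, ribosomal protein genes among them, were lower in the TMR vehicle library than in the other 3. Loss of short transcripts whatever their function would place the ribosomal protein median of 1.88 among lists matched in length. It lay at percentile 100 of them (their median 0.63, middle 95% 0.30 to 0.97). Those lists were not matched on expression, and lists matched on expression, but not on length, had a median of 0.72. With the length and GC trend removed the ribosomal protein median of 0.84 lay at percentile 100 of lists matched on expression. That trend was taken over genes of all expression levels, while ribosomal protein genes are both short and highly expressed. Whether length alone accounts for their shift therefore stays open. Short genes of other functions shared the shift in part, with 0.89 in the shortest 10% of transcripts without ribosomal protein and oxidative phosphorylation genes. A length correction by the authors that differed between the TMR libraries stays open: the ratio of bounds midpoint to FPKM differed by 0.021 on the log2 scale in the shortest 10%, but FPKM and its bounds would carry the same correction. Withdrawal of 4-OHT or its return acting on these genes in TMR, where the treated library differed from treated MCF-7 by -0.11, and a fault of 1 library cannot be told apart with a single TMR vehicle library.

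Interferon-response genes such as OAS2 and IFIT1 were higher in TMR. The length and GC trend was argued against by the median of 2.95 left after its removal, and dependence on the TMR vehicle library by the 3.14 of the comparison with 4-OHT, which does not use it. RNA of blood cells was argued against by their markers, of which 1 of 10 lay at FPKM 1 or more and 2-fold above MCF-7 with 4-OHT: HBA1, at 10.4 against 1.16, while HBB, PTPRC and CD3E were listed at 0 in TMR and CD68 had 1.52 in both lines. A stable difference between the cell lines may explain it, as a hypothesis from the same data, with 1 culture per group.

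Cell cycle genes such as BIRC5 and AURKB were lower after 4-OHT in MCF-7 and, on the deposited scale, not in TMR. With the length and GC trend removed the G2-M median in MCF-7 was -0.80, which argues against that trend. A fall in TMR hidden by the low short transcripts was argued against by the TMR median of -0.041 with the trend removed and 0.00092 in transcripts of at least 1500 nt. At the same total the G2-M median was -0.60 in TMR and -0.75 in MCF-7, but there the median of all genes was -0.51 in TMR; a fall in TMR and a scaling that lowers all genes cannot be told apart without counts or added standards. Drug resistance of the subline stays open and was not tested.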

How the results depend on the processing

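The trend removal, the limit of 1500 nt, failed estimates kept at 0, the removal of genes with little data and the line comparison without the TMR vehicle library were chosen after the data were seen; the other alternatives were set beforehand. With no replicates, a value counts as kept when it stayed within the interval that its bounds, its members or resampled genes give, and a count when it stayed within 1.5-fold. Of the list medians under all alternatives, 2393 were kept, 213 moved and 19 turned sign, the last counted only where the median lay beyond the random lists; of the single genes 7072, 2484 and 6; of the percentiles 319 were kept and 31 moved, and of the gene counts 133 and 35. Read depth is unknown, so what it limits could not be worked out. Unless the setting itself shows it, the cause was not tested. With a pseudocount of 0.1, genes at least 2-fold higher and lower in MCF-7 after 4-OHT were 142 and 160, those lower in TMR after 4-OHT 71 and those lower in the difference of responses 490. The correlation of responses was -0.20 and the covariance of the line difference with the MCF-7 response -0.020. The G2-M median was -0.98 in the MCF-7 response and 2.58 in the 4-OHT line comparison, where G1-S was 1.71 and interferon 3.85. C12orf5 (TIGAR) differed between lines by 1.24 with vehicle and 1.23 with 4-OHT, and PGR by 1.13 in the MCF-7 response and 2.63 between lines with vehicle. With a pseudocount of 5, which shrinks low genes, the MCF-7 counts were 32 and 16, those between lines with vehicle 626 and 1008, with 4-OHT 906 and 433, in both treatments 405 and 305, and those lower in the difference of responses 58. The correlation of responses was -0.34. G1-S was -0.50 in the MCF-7 response, 1.24 between lines with 4-OHT and 0.60 in the difference of responses; G2-M was -0.54, 1.73 and 0.58 there and 1.08 between lines with vehicle. Interferon was 1.84 and 2.13 between lines, C12orf5 0.33 and 0.32. ESR1 was -1.46 and PGR 0.79 between lines with vehicle, and PGR 0.22 in the MCF-7 response. In transcripts of at least 1500 nt, where fewer genes are counted, the MCF-7 counts were 39 and 33, the TMR counts 154 and 0, those lower between lines with vehicle 942 and those higher in the difference of responses 410; the correlation of responses was -0.35 and that covariance -0.022. Rescaled to the same total, 29 genes were lower in MCF-7, and counts were 324 and 1196 in TMR, 4131 and 875 between lines with vehicle and 438 and 2682 in the difference of responses; 24.3% of genes 2-fold different in MCF-7 had the same direction in TMR. Estrogen-induced genes were 0.32 in MCF-7, -0.59 in TMR and 1.42 between lines with vehicle. G1-S was -0.59 in MCF-7, -0.43 in TMR, 1.23 between lines with vehicle and 0.11 in the difference of responses, and G2-M -0.60, 1.96 and 0.14 in the last 3. NRF2 was -0.054 in MCF-7, and turned to -0.12 in TMR and -0.061 in the difference of responses. Also turned were luminal identity to 0.090 and glycolysis to 0.050 in MCF-7, NF-kB genes to -0.21 and histones to -0.041 in TMR, and antigen presentation to -0.061 and histones to -0.022 in the difference of responses. C12orf5 was 1.24 between lines with vehicle, NFE2L2 0.59 there and -0.22 with 4-OHT, ESR1 -0.39 in the MCF-7 response and -1.03 between lines with vehicle, and PGR 2.25. With the length and GC trend removed, counts were 195 and 271 in TMR and 348 and 458 in the difference of responses, the correlation of responses was -0.18 and NRF2 was 0.063 in TMR. Turned were luminal identity to 0.11, glycolysis to 0.0032 and histone methyltransferases to -0.017 in MCF-7, and histones to -0.18 in TMR and -0.37 in the difference of responses. Of single genes HBA1 turned to -0.068, HIST1H2BK to -0.17 and HIST1H2BD to -0.19 in TMR, and PGLS to -0.014, HSPB1 to -0.23 and HIST2H4A to -0.34 in the difference of responses. C12orf5 was 0.64 and 0.65 between lines and NFE2L2 -0.17 and -0.25. ESR1 was -0.61 in the MCF-7 response and -2.06 between lines with vehicle, PGR 0.44 and 1.07. Without the symbols recognised as small and non-coding RNA, which RMRP and RPPH1 are not, 4 genes were lower in TMR after 4-OHT and the correlation of responses was -0.37; with bounds that do not overlap 9 were lower. By median of ratios 328 genes were lower in the difference of responses, luminal identity turned to 0.0068 and glycolysis to 0.0098 in MCF-7, and housekeeping genes to -0.0083 between lines with vehicle. C12orf5 was 0.69 and NFE2L2 -0.26 between lines with 4-OHT. At the same upper quartile 531 genes were lower in the difference of responses, and luminal identity turned to 0.042 and glycolysis to 0.028 in MCF-7. G1-S and G2-M were -0.018 and -0.17 in TMR and 0.60 and 0.63 in the difference of responses. Between lines with 4-OHT NRF2 was -0.24, G2-M 2.06, C12orf5 0.64 and NFE2L2 -0.34, and ESR1 was -0.44 in the MCF-7 response. Without the TMR vehicle library 1932 genes were higher in TMR, since only 1 comparison then has to pass. With the mean in place of the median, housekeeping genes turned to -0.040 between lines with vehicle.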

Other observations

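The genes of the next paragraph were chosen after their values were seen, while the test of neighbouring genes in the last one was set down before its result was seen.

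Some genes had FPKM of at least 5 in both libraries of 1 line and under 0.1 in both of the other. A total of 28 genes had FPKM of at least 5 in both TMR libraries and under 0.1 in both MCF-7 libraries. They included IL24, a cytokine near IL20 on chromosome 1, at 13.1 with vehicle and 17.6 with 4-OHT in TMR and listed at 0 in MCF-7. PRAME, a cancer-testis antigen, had 20.5 and 19.8 in TMR, SAGE1, of the same class, 14.7 and 11.2, and CT45A5, with close paralogs, 13.2 and 18.3. The imprinted genes DLK1, MEG3 and PEG10 had 10.1, 8.15 and 16.7 with vehicle, and GJA1 (connexin 43) 8.55. In the other direction 17 genes were found: SHH, the hedgehog ligand, had 5.83 and 9.28 in MCF-7, BMP5, a bone morphogenetic protein, 15.3 and 16.8, GRIK2, a glutamate receptor, 9.66 and 10.2, DPYD, which degrades pyrimidines, 6.33 and 6.80, and MEIS2, a homeobox factor, 5.39 and 6.52, listed at 0 in TMR. Whether the lines share their origin was not examined here.

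Differences between the lines were also shared by neighbours on a chromosome; the medians and shares below have the length and GC trend removed. With 4-OHT the 31 genes from HARS to PCDHGB5 on chromosome 5 (140053490 to 140892546, hg19), which hold the clustered protocadherins, had a median of -1.26, and those from IRX2 to GOLPH3 on that chromosome (2746279 to 32174425) -1.09. The 31 genes from PEX6 to AARS2 on chromosome 6 (42931611 to 44281063) had 0.99, and those from ZNF595 to HAUS3 on chromosome 4 (53227 to 2243860) -1.05. In the order given, 25, 28, 27 and 22 of the 31 genes had the direction of the median with 4-OHT. WHSC1 lies by its coordinates in the span on chromosome 4 and was higher in TMR on the deposited scale. Chromosome segments at different copy number in the lines may be one reason: 2.26% of 11803 windows of 31 genes had medians beyond all 100 shuffles of gene order, against 1.71% with vehicle, 0.017% in the MCF-7 response and 0.26% in the TMR response. That share lay between the bounds set for and against this explanation, so copy number and shared regulation of neighbours, such as the protocadherin cluster, cannot be told apart without DNA data.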
